A study of Mus musculus with 143 samples.

How the data were processed

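Deep single-cell RNA-seq was made from microglia of the cerebellum of mice at postnatal day 7. Per the labels' protocols, cerebella of male C57BL/6N animals were pooled, dissociated mechanically and sorted as single cells into wells of plates through a gate for low CD45, CD11b, Gpnmb and Clec7a, and libraries were made with Smart-seq2, a full-length method without molecular identifiers. The data hold 143 cells, 95 on a plate called plate 1 here and 48 on a plate called plate 2. The age label and the series title give postnatal day 7, which was used, although a pooled library name in the labels contains the word adult. All cells carry the same group labels and come from a pool of animals whose cells cannot be assigned to an animal, so the series was treated as 1 sample, and the plates as technical batches.

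The authors deposited 1 table of whole-number read counts per gene and cell, with 23429 rows. The rows comprise 23337 gene rows, among them the ribosomal RNA precursor Rn45s, and 92 spike-in rows of the External RNA Controls Consortium (ERCC). Of the gene rows, 12801 had a count in at least 1 cell, and the table has 0 mitochondrial rows under the usual name prefix. The submitters' processing notes name Trim Galore 0.4.3, STAR 2.5.3a, Picard and HTSeq and the genome build mm10, without their order or settings; the gene annotation is not given in the sources used here. Whether reads were counted by strand is likewise not given, so genes that overlap or have near-identical copies, ferritin light chain and several ribosomal protein genes among them, carry that uncertainty. The sum of each column, spike-ins included, equalled the total count in the labels in 143 of 143 cells. No pair of cells had identical values.

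CPM, counts scaled to 1000000 gene counts per cell, were computed here from the deposited counts, with spike-ins left out and Rn45s kept in. Pooled CPM is the sum of a gene's counts over cells divided by the sum of all gene counts. Counts were not divided by gene length, so levels of different genes are shares of reads, not of molecules. No cell was removed. Total counts per cell ran from 271190 to 1226521. Each share of cells is the share with at least 1 count, with an exact Clopper-Pearson 95% interval. These intervals, and ratios with their counting intervals, cover counting error only. Reads of the same molecule are not independent, and spread between animals cannot be seen in a single pool. For a gene seen in 0 of 143 cells, the exact interval ends at 2.55%, and the simpler limit of 3 counts of the total is 2.10%.

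Because cells are not replicates, no test was run between groups of cells and no p-value is given. Before the data were examined, the gene lists, the markers of other cell types, the settings and the rule for named genes had been fixed. The rule takes the members of the gate, PAM and DAM and homeostatic lists, the 15 genes with the highest pooled CPM that are neither mitochondrial nor ribosomal protein genes, and the 20 most variable genes with a pooled CPM of 10 or more. It also takes the leading 2 to 4 members of each other list, any marker of another cell type with a read in over 20% of cells, the 10 leading genes of each cluster, and the 10 genes with the largest ratio between plates. A few genes that meet the rule are left out of the text, though they count in the lists. Older symbols are printed as the file gives them. Genes of the remaining list members and of the lists in the closing section were named after their values were seen.

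Variability was the squared coefficient of variation of CPM over cells, for 7789 genes with a read in at least 10% of cells. It was divided by a running median over 201 genes ordered by mean CPM, and the log2 of that quotient is called the excess. A list's median excess was placed among 10000 random lists of the same size, each gene drawn from the 100 genes on either side in mean CPM. As a technical reference, 45 spike-ins scaled to the spike-in total of their well gave a monotone curve of squared coefficient of variation against abundance.

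A cell was placed in a cycling class when at least 6 of the 24 S genes or 8 of the 31 G2/M genes had a CPM of 10 or more. Clusters were made from log1p of counts per 100000, the 1000 genes with the largest excess, 15 principal components and 15 neighbours, with the Leiden method at resolution 0.6 and a fixed seed. Cluster 1 is the cluster with the highest G2/M mean, and clusters 2 and 3 are numbered by falling homeostatic mean. No doublet caller was run, since cells were sorted singly into wells. List ratios between clusters are medians over genes with a pooled CPM of 10 or more, computed on pooled CPM + 1.

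The steps were tested on simulated counts drawn from the means, depths and trend of spread of the 23337 genes. With 200 genes raised 4-fold in a random 20% of cells, 83.5% of them fell in the top 10% of 9656 ranked genes. With 8-fold it was 97.5%, with 9603 genes ranked. These rates are over all raised genes and were not split by the share of cells with a read. Recovery is therefore not shown for genes read in few cells, such as Cdc20 (13.3% of cells) and Mmp12 (14.0%) in the measured data. A planted group of 25 cells with 150 genes raised 6-fold was recovered whole, and with 60 genes 24 of its cells were. Simulated cells of a single kind were still divided into 3 clusters, with a silhouette of 0.034, so a number of clusters alone does not show kinds of cells.

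Alternatives covered the detection limit, thinning to 200000 counts per cell, filters on cells, single plates, other scalings and other clustering settings, and their effect is given in the closing section. For variability, the value compared was first the number of genes over a fixed excess; it was replaced, after its results had been seen, by how many of the 20 named genes stay in the leading 20, because counts of genes made from cells are not reported here. List ratios between clusters, and all their alternatives, were chosen after seeing the data. They were cut to a subset after their sign changes had been seen, and then restored in full, for 11 lists and 3 pairs of clusters; the immediate early and border-associated macrophage lists were added last. Gene positions are from GENCODE M21 on GRCm38, the assembly also called mm10. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.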

Results

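Single microglia, the resident macrophages of the brain, were sequenced from the cerebellum of mouse pups at postnatal day 7. The gate took cells with both Gpnmb and Clec7a on their surface, a phenotype of microglia in developing white matter that the protocol label names proliferative-region-associated microglia (PAM). The series asks what such cells express. It holds 143 cells of 1 group from a pool of animals, 95 on plate 1 and 48 on plate 2, and no other population, so levels within the gate are described and nothing is said to be higher or lower than in other microglia. The median total was 760690 counts per cell, with quartiles of 661298 and 827296. The median number of genes detected was 3255, with a range of 1552 to 4955. Spike-ins took a median of 3.86% of counts and the ribosomal RNA precursor Rn45s 9.28% of all gene counts, 8.32% on plate 1 and 11.3% on plate 2.

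The RNA of the gate was counted first, as a check of the label. Gpnmb, a transmembrane glycoprotein of macrophages, had a read in 98.6% of cells (95% interval 95.0 to 99.8), with a median of 3420 CPM and quartiles of 2115 and 5287. Clec7a, the receptor for fungal beta-glucans also called Dectin-1, had a read in 83.2% of cells (76.1 to 88.9) with a median of 331 CPM. Both were read in 82.5% of cells (75.3 to 88.4), where independent detection of the 2 genes would give 82.1%, and 1 cell had neither. Ptprc, which encodes CD45, was read in 76.2% of cells and Itgam, which encodes CD11b, in 67.8%; all 4 genes were read in 64 cells (44.8%). Gpnmb lies on the plus strand of chromosome 6 from 49036546 to 49070929 and Clec7a on the minus strand of the same chromosome from 129461591 to 129472779, where the annotation gives its type as polymorphic pseudogene. The sort was on protein, so a cell with no read of a gate gene is not thereby outside the gate.

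Genes of the PAM signature, shared with the disease-associated microglia (DAM) of injured and ageing brain, were detected widely but not uniformly. Of the 26 listed genes, 17 had a read in at least 90% of cells and 23 in at least 50%, the median share over genes was 97.2%, and the list took 11.4% of all gene counts. Spp1, the secreted matrix protein osteopontin, had a median of 46105 CPM (quartiles 30171 and 59293), and Apoe, the lipid carrier, 32508 CPM (24826 and 42648). Spp1 (chromosome 5, 104435118 to 104441050, plus strand) and Apoe (chromosome 7, 19696109 to 19699188, minus strand) were read in every cell. So were Igf1, a growth factor, at a median of 1114 CPM, the tetraspanins Cd9 at 5256 and Cd63 at 2594, and Ctsl, Ctsz, Cd68 and Syngr1. Lpl, lipoprotein lipase, and Plin2, a coat protein of lipid droplets, were each read in 98.6% of cells. Detection was partial for Itgax, which encodes CD11c (52.4%, 43.9 to 60.9), and Ccl3 (54.5%), and low for Cst7 and the receptor tyrosine kinase Axl (22.4% each) and for Ccl4 (19.6%). The list is related to the gate by its choice, so its detection is not independent of the sort.

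**Figure D1:**
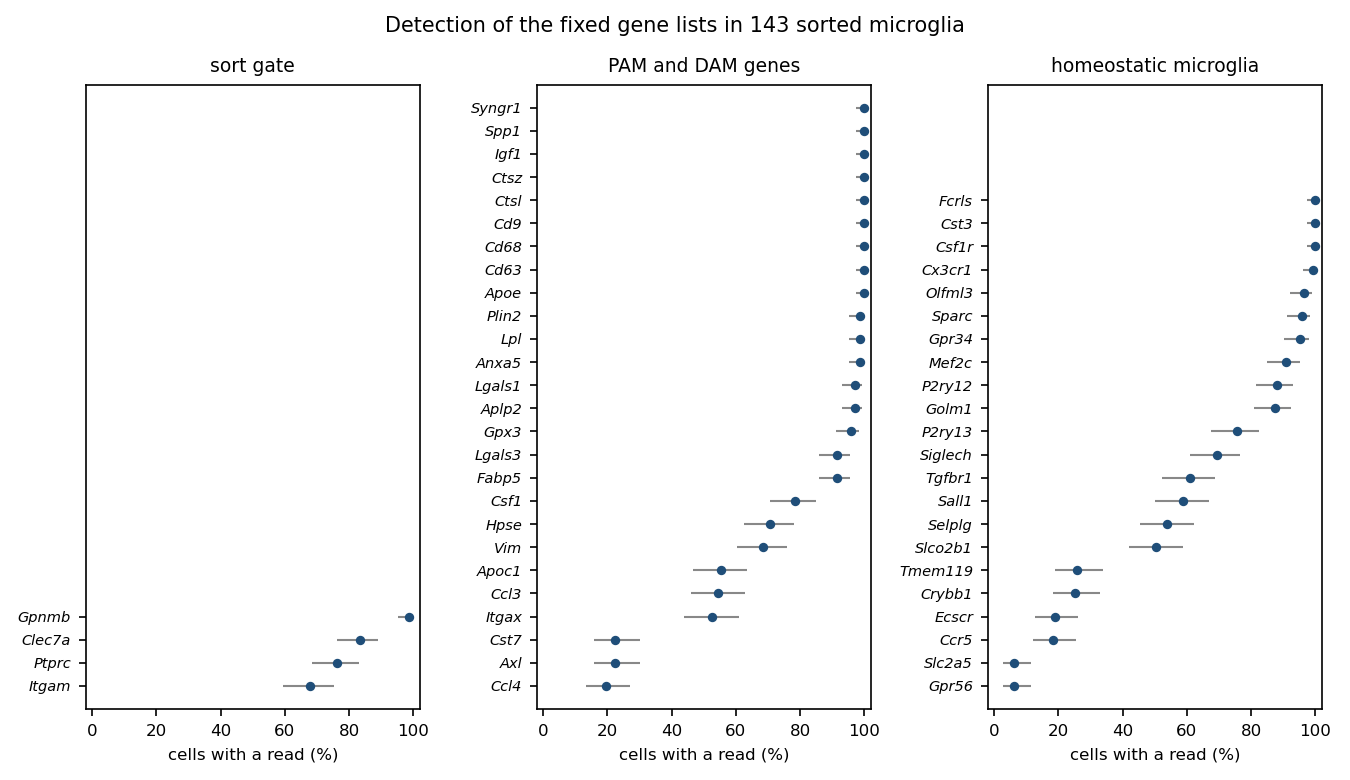
Share of the 143 cells with a read (x axis, percent) for genes of the sort gate, the PAM and DAM list and the homeostatic list (y axes; 1 gene of the last is not drawn); points are shares and bars exact 95% intervals that cover counting error only. The lowest share is 19.6% in the PAM and DAM list and 6.29% in the homeostatic list.

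Genes of homeostatic microglia were present beside them, with a wider range of detection. Of 23 measured genes, 9 had a read in at least 90% of cells and 17 in at least 50%, with a median share of 75.5% and 2.45% of all gene counts. Csf1r, the receptor on which microglia depend for survival, was read in every cell at a median of 1719 CPM, as were Fcrls at 3312 and the protease inhibitor gene Cst3 at 3380. Cx3cr1, the fractalkine receptor, was read in 99.3% of cells at a median of 3414 CPM. P2ry12, a purinergic receptor of surveying microglia, was read in 88.1% of cells (81.6 to 92.9) at a median of 295 CPM. Sall1, a transcription factor of microglial identity, was read in 58.7%. The lowest members were Tmem119 at 25.9% (18.9 to 33.9), Crybb1 at 25.2%, and Slc2a5 and Gpr56 at 6.29% each.

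Lysosomal genes were among the most abundant, and phagocytic genes varied widely in level. Of 25 lysosomal genes, 22 were read in at least 90% of cells, the median share was 100%, and together they took 9.97% of gene counts, led by the proteases Ctsb (21734 pooled CPM) and Ctsd (18596). The phagocytic list took 1.11% of gene counts and had a median share of 64.3%, with Trem2, its adaptor Tyrobp and Fcer1g in every cell. The complement list split between the C1q genes C1qa, C1qb and C1qc, each in every cell, and C3, C4b and Cfp, each in under 3 percent. The lipid list had a median share of 63.3%, with Apoe, the sterol acyltransferase gene Soat1 and Npc2 in every cell and the exporter Abcg1 in 99.3%. Glycolysis genes had a median share of 94.4%, with Ldha at 2492 and Pkm2 at 2974 pooled CPM, and nuclear-encoded genes of oxidative phosphorylation 95.8%, with Cox4i1 and Atp5j2 in every cell.

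Inflammatory genes were sparse. The chemokine and cytokine list had a median share of 15.4%. Ccl9 (82.5%) and Ccl6 (76.2%) were frequent, while Tnf was read in 3 cells, Il1b in 1 cell, and Il6, Il10 and Cxcl10 in 0 of 143. Interferon response genes had a median share of 2.80%, with Bst2 at 69.2% and Ifi27l2a at 20.3%. Immediate early and stress genes had 7.69%, led by Klf6 (55.2%) and Nfkbia (43.4%), with Fos in 4 cells. MHC class II genes had 17.5%, led by H2-DMb1 (42.0%) and Cd74 (35.7%), and MHC class I genes 81.1%, led by B2m (100%) and H2-D1 (97.2%). Secreted growth factors had 6.99%, with Grn in every cell and Csf1 in 78.3%.

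Markers of other cell types were rare. Across the 14 lists for other cells the highest median share was 8.74%, that of border-associated macrophages. Its members Stab1, a scavenger receptor, and Mrc1, the mannose receptor, were read in 87.4% and 55.9% of cells and Ms4a7 in 21.0%, while Cd163, Lyve1 and Cd209f were read in 0 of 143. In the oligodendrocyte list Cnp was read in 35.7% of cells (27.8 to 44.1), Mbp in 13.3% and Mag in 10.5%, with Mog, Mobp and Cldn11 in 0. Among the other lists, Slc1a3 led the astrocyte markers at 13.3%, Rbfox3 the neuronal ones at 5.59%, Flt1 the endothelial ones at 10.5%, Fn1 the monocyte ones at 15.4%, Zbtb46 the dendritic cell ones at 4.20% and S100a8 the neutrophil ones at 6.99%. Cd79b, of the B-cell list, was read in 37.1% of cells, while Cd79a, Ms4a1 and Pax5 were read in 0.

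By read share alone, Rn45s, Spp1, Apoe, Ctsb and Ctsd led, followed by the ferritin light chain gene Ftl1 (9860 pooled CPM), Actb, Lgmn, Ctsz, the selenoprotein gene Sepp1 (5868), Ctsa, Cd9, Ctsl and C1qb. The leading 15 genes, of which 14 are named here, took 27.5% of gene counts. Rn45s and Sepp1 have no exon length in the annotation used; of the other 13, 11 stayed among the leading 15 when levels were divided by exon length, and Ctsa and Ctsl fell to ranks 24 and 40.

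Ranked among 7215 genes with a read in at least 10% of cells and a pooled CPM of 10 or more, 7 of the 20 genes that differed most between cells belong to the cell cycle lists. Plau, the urokinase-type plasminogen activator, had the largest excess of variability, 3.47 log2 units over the trend (3.57 on plate 1 and 0.81 on plate 2); it was read in 32.9% of cells and 5 cells held 53.2% of its summed CPM. The cell cycle genes among them included the mitotic genes Cdc20 (2.54), Mki67 (2.18) and Top2a (1.83) and the DNA synthesis gene Rrm2 (2.26). Atp6v0d2, a subunit of the vacuolar proton pump, had an excess of 2.13, the macrophage metalloprotease Mmp12 1.83, the galectin gene Lgals3 1.79 with a read in 91.6% of cells, and the chemokine gene Ccl9 1.65. P2ry12 stood at 1.63, but at 1.83 on plate 1 and 0 on plate 2. The other 10 of the leading 20 were Zfp36, Hgsnat, Fam20c, C2, Mcm6, Birc5, Cenpe, Hspa5, Slc39a2 and Hbp1. Zfp36, of the immediate early list, had 73.1% of its summed level in 5 cells, with an excess of -0.36 on plate 1 and 2.38 on plate 2.

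Whole lists differed in the same measure. The chemokine and cytokine list had the largest median excess over all cells, 0.89, but on neither plate alone (0.46 on plate 1 and 0.85 on plate 2). On plate 1 the G2/M list was higher, at 0.88. The border-associated macrophage list had 0.69 (percentile 99.9), with 0.64 on plate 1 and 0.96 on plate 2. The G2/M list had a median excess of 0.85 and the S list 0.53, each above all 10000 matched random lists, but by the variance of log2(CPM + 1) the G2/M list fell to percentile 0 and the S list to 86.8. The PAM and DAM list had 0.39 (percentile 99.99) and the homeostatic list 0.38 (99.8, and 94.2 on plate 2 alone). Lysosomal genes had -0.80 (percentile 0.01), oxidative phosphorylation -1.34 and ribosomal proteins -2.10, both below all random lists. Immediate early genes had 0.66 over all cells, but on plate 1 alone their percentile was 57.6. Against the spike-ins, the G2/M genes lay at a median of 1.76 log2 units above the technical curve, the PAM and DAM genes at 1.58 and all 7748 genes in range at 0.70; lysosomal genes, low against genes of like abundance, still lay at 1.82. Oxidative phosphorylation genes at -1.08 and ribosomal proteins at -1.43 lay below the curve, so it is not a floor of technical noise for genes.

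**Figure D2:**
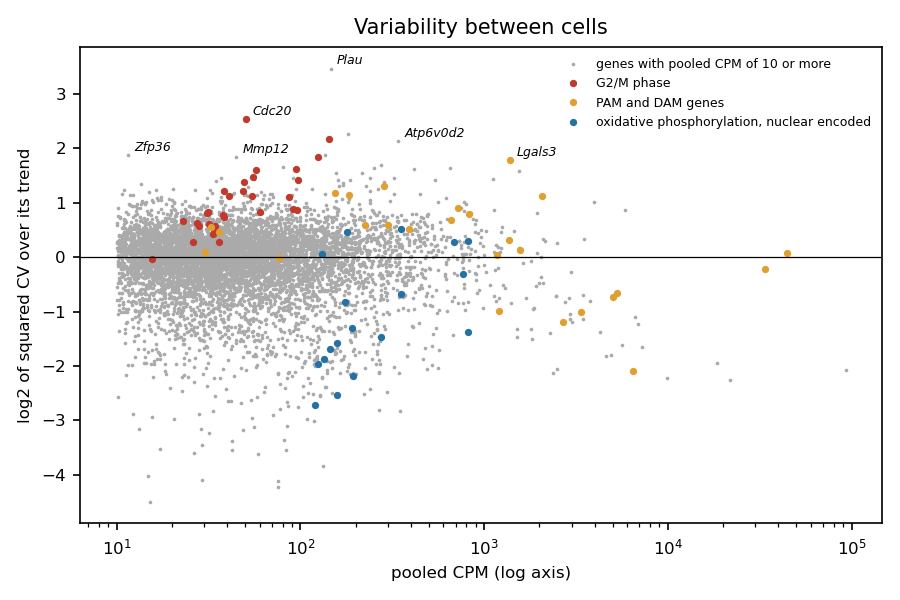
Log2 of the squared coefficient of variation of CPM over its running median trend (y axis) against pooled CPM (x axis, log scale), 1 point per gene over 143 cells, with 3 lists in colour. The G2/M genes lie mostly above the line at 0, with a median of 0.85, and the oxidative phosphorylation genes mostly below it, with a median of -1.34.

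A large share of the sorted cells carried cell cycle transcripts. The cycling class held 63 of 143 cells (44.1%, 35.8 to 52.6), 46 of 95 on plate 1 (48.4%) and 17 of 48 on plate 2 (35.4%, 22.2 to 50.5). The G2/M limit was met by 30 cells (21.0%) and the S limit alone by 33 (23.1%). The most frequent members were Pcna, the polymerase clamp, in 60.8% of cells, Mcm3 of the replicative helicase in 55.9%, Slbp in 55.2%, and Cdk1 and Smc4 in 34.3% each. The class is a range and not a type: 26 cells lay within 2 genes of a limit.

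**Figure D3:**
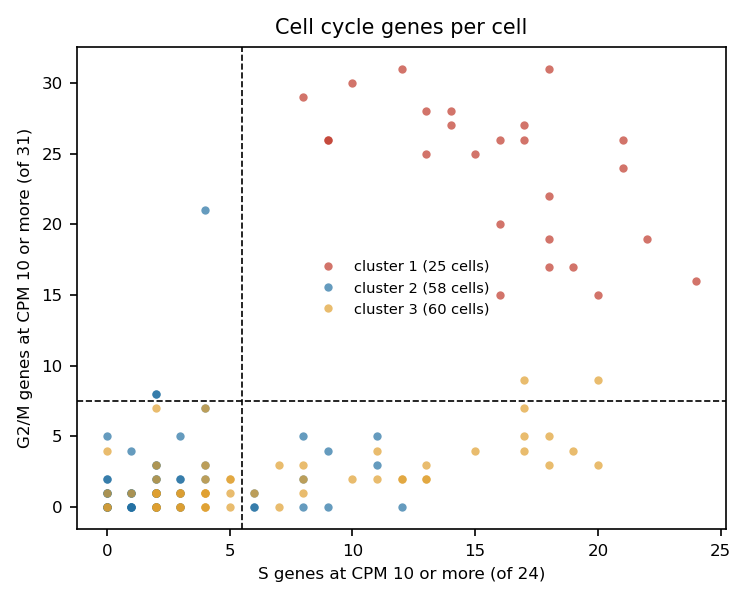
Number of S genes (x axis, of 24) and G2/M genes (y axis, of 31) with a CPM of 10 or more in each of 143 cells, coloured by cluster, with dashed lines at the limits of the cycling class. The cells of cluster 1 have a median of 26 G2/M genes, the other cells a median of 1.

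Clustering gave 3 clusters, of which 1 was set apart by G2/M and S genes; simulated cells of a single kind also gave 3. Cluster 1 held 25 cells (17.5%, 11.6 to 24.7), all in the cycling class. It is called G2/M-like, since 17 of the 31 G2/M markers were among its 50 leading genes, though only 2 were among its 10 leading genes. The rule fixed beforehand asked for at least 3 markers among the leading genes, so the name rests on the wider window. Its cells had a median of 16 S genes at a CPM of 10 or more, against 3 in the other cells, and the S list had a median log2 ratio of 3.22 over cluster 2 and 1.46 over cluster 3. Its 10 leading genes were Kif2c, Esco2, Anln, Shcbp1, Cdca2, Oip5, Nusap1, Neil3, Pbk and Aspm, genes of spindle, cytokinesis and chromosome segregation or of replicating cells. Esco2, which acetylates cohesin, was read in 68% of its cells and in 0 of the others, at least 2318-fold higher against the floor of 3 counts, and Anln in 76% against 1.69%. The other cells fell into cluster 2, with 58 cells (40.6%), and cluster 3, with 60 (42.0%), which are left as numbers. Cluster 3 had 3 PAM and DAM genes among its 50 leading genes and 0 among its 10, and was not named on the wider window. Both plates contributed to each cluster, with 18 and 7 cells in cluster 1, 35 and 23 in cluster 2, and 42 and 18 in cluster 3.

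**Figure D4:**
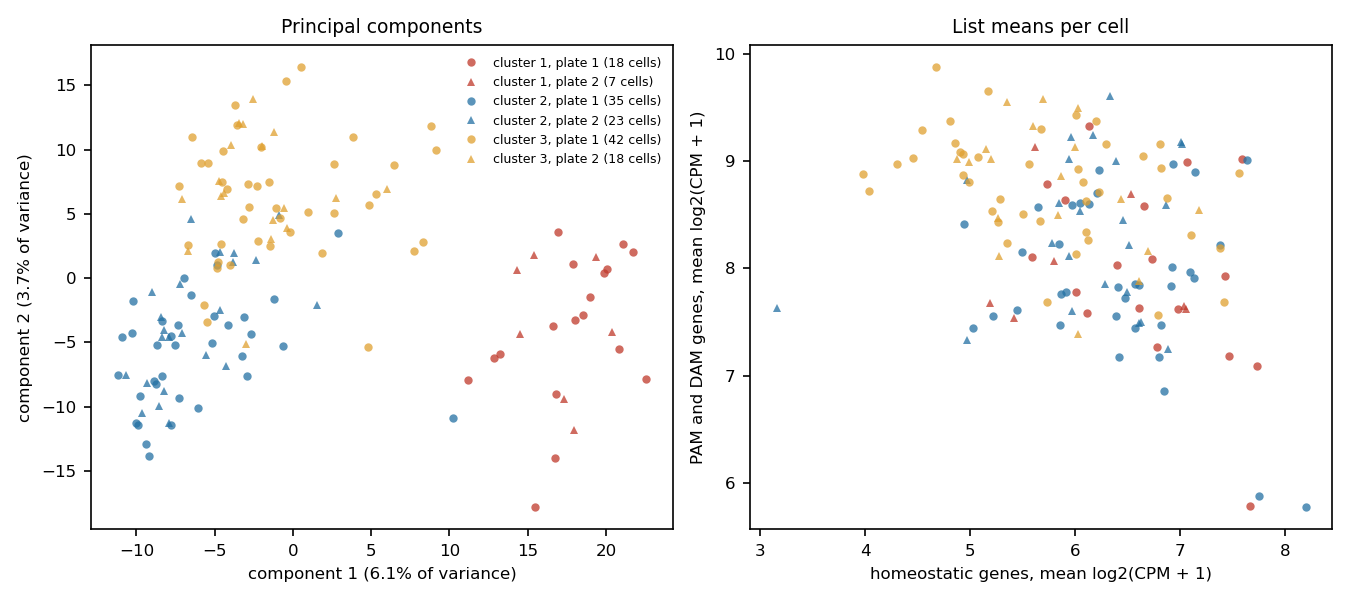
Left, the first 2 principal components of 143 cells, and right, the mean log2(CPM + 1) of the homeostatic genes (x axis) and of the PAM and DAM genes (y axis) in each cell, with colour for cluster and shape for plate. The first component takes 6.08% of the variance and the second 3.67%; clusters 2 and 3 border on each other in both panels.

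Cluster 2 is, by the way the clusters are numbered, the one with more of the homeostatic genes, and cluster 3 carried more of the PAM genes. The median log2 ratio of cluster 3 over cluster 2 was 0.29 over 26 PAM and DAM genes (0.27 on plate 1 and 0.22 on plate 2) and -0.40 over 22 homeostatic genes (-0.47 and -0.13). Of the PAM and DAM genes, 17 were higher on both plates, 5 were lower on both and 4 differed between plates. Among the homeostatic genes, 15 were lower on both, 4 higher on both and 3 differed. Median Lgals3 was 1611 CPM in cluster 3 and 545 in cluster 2, Lpl 2581 and 960, Fabp5 550 and 193, and Igf1 1430 and 1034. In the other direction, pooled P2ry12 was 209 CPM in cluster 3 and 565 in cluster 2, median Csf1r 1524 and 2734, and median Apoe, itself of the PAM list, 29031 and 40840. Some homeostatic genes went against their list and were higher in cluster 3 on each plate, Crybb1 at 17.6 against 15.5 pooled CPM on plate 1 and 73.5 against 8.56 on plate 2, and Tmem119 at 95.3 against 54.9 on plate 1 and 22.9 against 13.3 on plate 2. The median log2 ratio of cluster 3 over cluster 2 was 0.58 for glycolysis genes (0.63 and 0.52) and 0.79 for 8 immediate early and stress genes (0.26 and 1.13). It was 0.54 for 10 chemokine and cytokine genes, 6 of them higher on both plates, and 0.56 for 4 MHC class II genes, 2 of them higher on both. S genes were at 1.66 (1.77 and 1.09), but G2/M genes were at -0.37 (-0.585 and 0), with 9 lower and 4 higher on both plates. The cycling class held 24 cells of cluster 3 and 14 of cluster 2. Of the border-associated macrophage markers, 6 could be compared, Mrc1 and Stab1 among them, with a median of -0.87 (-0.79 and -1.07). Of these, 4 were lower in cluster 3 on both plates and 2 differed between plates. The leading genes of cluster 3 were Slc39a2, Fam20c, Furin, Tmem184b, Rhoc, 5430435G22Rik, Gnptab, Slc15a3, Gp49a and Eif1a, with fold differences in pooled CPM over the other cells between 2.78 and 8.37. Those of cluster 2 were Ypel3, Ptplad2, Slc46a3, Abca9, Il10ra, Slc40a1, Trrap, Ms4a6b, Mrc1 and Lpcat2, with fold differences between 2.67 and 4.89, though on plate 2 alone Il10ra was at 1.29 and Ms4a6b at 1.27.

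The clusters also differed in RNA recovered relative to spike-ins. Gene counts per spike-in count had medians of 29.5 in cluster 1, 20.2 in cluster 2 and 25.6 in cluster 3 on plate 1, and 32.1, 22.5 and 27.9 on plate 2. The numbers of genes detected had medians of 3761, 2888 and 3336. Scaled to spike-in totals, the ratio of cluster 3 over cluster 2 was 0.63 for the PAM and DAM genes and -0.052 for the homeostatic genes. Lysosomal genes, at -0.17 in CPM, turned to 0.17, and the complement, MHC class I and phagocytic lists turned in the same way. For cluster 1 over cluster 3 in CPM, the median log2 ratio was -0.45 for the PAM and DAM list (-0.49 and -0.46 by plate), -0.37 for the lipid list and 0.26 for homeostatic genes (0.37 and 0.042). Scaled to spike-in totals, these were -0.20, -0.12 and 0.51.

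The clusters were cut from the same cells whose genes they are described by, so their leading genes define them. The silhouette was 0.137, against 0.024 to 0.043 in 20 data sets with each gene shuffled over the cells of a plate. Shuffling also removes differences between cells in genes detected, so the comparison cannot tell kinds of cell from amounts of RNA recovered. Across cells, the first principal component had r = 0.65 with the number of genes detected. The median silhouette over cells was 0.276 in cluster 1, 0.181 in cluster 3 and lowest in cluster 2, at 0.046. No such medians were computed for the shuffled data, whose range is of means over all cells, so they cannot be set against it. Cluster 2 against cluster 3 alone gave a silhouette of 0.112. Over 20 seeds the 25 cells of cluster 1 always stayed together, while agreement with the reported clusters, as the adjusted Rand index, had a median of 0.705 and a lowest value of 0.415, so the line between clusters 2 and 3 is soft.

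The plates, technical batches of the sort, were close for abundant genes and apart for rare ones. Across 7616 genes with a pooled CPM of 10 or more, which are not independent replicates, log2 pooled CPM on the plates had r = 0.914 and the median absolute log2 ratio was 0.34. Among the 84 genes with a pooled CPM of 1000 or more the largest absolute log2 ratio was 0.45. The largest ratios belonged to genes read in few cells. Ttc30b, Cyth3 and Fmo5 were higher on plate 1 and had 1 to 3 counts on plate 2, with a ratio of 230 for Fmo5 (counting interval 78.5 to 1115). Zfp81, A130022J15Rik, Zfp873, BC088983, Nod1 and Polr3g had 0 counts on plate 2 and were at least 162-fold to 191-fold higher on plate 1, against a floor of 3 counts over the plate. Zfp746 was higher on plate 2 (counting interval of the ratio 86.7 to 240), where it was read in 9 cells.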

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

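Besides the alternatives fixed before the data were examined, those without cluster 1, without Rn45s, with spike-in totals as factors, with 20 seeds, and with the PAM and homeostatic genes left out of clustering, every alternative of the list ratios, and the measure of overlap for variable genes were chosen after seeing the data. The shares of cells with Gpnmb and Clec7a and the median shares of the PAM and DAM and of the homeostatic genes stayed within their intervals under all 8 alternatives each, and 7 of the other 28 lists had a median share of 50% or more under each of 7 alternatives. Of 2793 shares of single genes, 154 left their interval, and of 196 median shares of the other lists 9 did, all in the neuron, neutrophil and erythroid lists, which fell to 0. The share in the cycling class was 21.0% with the G2/M list only, which by construction drops cells that met the S limit, and 35.4% on plate 2 only, where the cause was not tested. Of the 20 most variable genes, 11 stayed in the leading 20 among genes in at least 30% of cells, a filter that removes the others by construction, 9 on plate 2 only, 3 by the variance of log2(CPM + 1) and 13 without cluster 1. By the variance of log2(CPM + 1) the G2/M list fell to percentile 0 of matched lists; the cause was not tested. Of 174 percentiles, 14 more crossed a limit, among them the homeostatic list at 84.4 and the S list at 86.8 by the same measure. The number of clusters was 7 at resolution 1.0 and from 2 to 4 under the other alternatives, and the 25 cells of cluster 1 stayed together under each. The median absolute log2 ratio of the plates was 0.22 for genes with a pooled CPM of 50 or more and 0 for medians of cells' CPM + 1, since many genes have a median of 0. Of 195 alternatives of list ratios between clusters, 22 changed sign, 17 of them with spike-in totals as factors, which add the difference in gene counts per spike-in count to every gene. With these factors, cluster 3 over cluster 2 turned to 0.17 for lysosomal, 0.19 for complement, 0.078 for MHC class I and 0.13 for phagocytic genes. Cluster 1 over 2 turned to 0.41 for PAM and DAM, 0.58 for homeostatic, 0.27 for lysosomal, 0.46 for lipid, 0.44 for complement, 0.37 for MHC class I, 0.36 for phagocytic and 0.20 for immediate early genes. Cluster 1 over 3 turned to 0.14 for glycolysis, 0.11 for lysosomal, 0.13 for MHC class II, 0.20 for cytokine and 0.17 for phagocytic genes. On plate 2 only, cluster 1 over 3 turned to -0.20 for complement, -0.17 for MHC class I and 0.23 for MHC class II, and cluster 1 over 2 to -0.23 for cytokine genes; on plate 1 only, cluster 1 over 3 turned to 0.26 for cytokine genes, where the cause was not tested.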

Other observations

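Further gene groups, listed after the data had been seen, describe these cells in other respects. Of 12 iron handling genes, 6 were read in at least 50% of cells: the ferritin genes Ftl1 (9860 pooled CPM) and Fth1 (2912) were read in every cell and transferrin, Trf, in 93.7%, and Slc11a1 in 68.5%, with Hmox1 and Slc40a1 the others, while the transferrin receptor Tfrc was read in 5.59%. The iron exporter gene Slc40a1 was read in 72.4% of cells in cluster 2 and 40% in cluster 3, and Hmox1, which degrades haem, in 62.1% and 70%. Of extracellular proteases and inhibitors, Timp2 and Adam10 were each read in 96.5% of cells and the urokinase receptor Plaur in 70.6%. Plau was read in 50% of cells in cluster 3, at a median of only 5.66 CPM, and in 17.2% in cluster 2, and Mmp12 in 26.7% and 3.45%. Most of the summed level of each lay in 5 cells, and Mmp9 and Timp1 had 0 counts in all 143 cells.

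Pattern recognition genes had a median share of 26.6%, with the lipopolysaccharide co-receptor Cd14 in 88.8% of cells, Tlr7 in 67.8%, Tlr2 in 60.1% and Tlr4 in 25.9%. Purinergic receptors had a median share of 76.2%. P2ry12 and P2ry13 were at 565 and 454 pooled CPM in cluster 2 and at 209 and 220 in cluster 3, while P2rx4 was at 335 and 305. Of myeloid transcription factors, Irf8 was read in 89.5% of cells and Maf in 83.2%. Bhlhe40, read in only 18 cells, was at 49.8 pooled CPM in cluster 3 (25% of its cells) and 1.47 in cluster 2 (1.72%). Sall1 was at 49.7 in cluster 3 (50%) and 157 in cluster 2 (74.1%).

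Of the tests below, those of the homeostatic genes, of plates and of macrophage markers were chosen after the result had been seen; that of PAM genes in pairs was written before, and the homeostatic genes were split from it afterwards. The series has a single group, so no biological explanation was tested for either of the 2 patterns.

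Cluster 3 lay above cluster 2 in PAM and DAM genes and below it in homeostatic genes, the latter direction being set by the numbering of the clusters. A difference of plates is argued against, since the PAM list was higher in cluster 3 on each plate, the smaller median log2 ratio being 0.22. Lower RNA recovery in cluster 2 may account for part of the PAM difference. Clusters were built without either list, and 35 pairs of cells were matched on gene counts per spike-in count. The median of the paired differences in mean log2(CPM + 1) was 0.39 (quartiles -0.063 and 0.98), with 25 of 35 pairs still higher. The unpaired value, 0.89, is the difference between the medians of all 73 cells like cluster 3 and all 44 like cluster 2. Against it, the paired value was under the limit written beforehand by a small margin. The paired cells like cluster 3 were a subset with a median of 21.7 gene counts per spike-in count, against 25.8 in all 73. Statistic and cells both changed, so the fall cannot be put down to matching alone. Homeostatic genes were lower in the cells like cluster 3 in 29 of 35 pairs, a direction largely set by choosing both groups for their overlap with clusters 2 and 3. The median of the paired differences was -0.70 (quartiles -1.08 and -0.25), so the difference was still present in pairs of like recovery. The difference between the medians of all 73 and 44 cells was -0.55. It is another statistic on more cells, so the sizes cannot tell what recovery accounts for. Scaled to spike-in totals, the ratio of cluster 3 over cluster 2 for these genes was -0.052, against -0.40 in CPM. Whether cells with less RNA lost it in the well or held less of it stays open, as does stress of dissociation, which was not tested, with immediate early genes at 0.79 in cluster 3 over cluster 2. The cell cycle was not tested either, although clusters 2 and 3 also differed in S genes. With S and G2/M genes left out of the variable genes, 3 clusters were found, with an adjusted Rand index of 0.49 with the reported clusters. The lowest index among seeds that also gave 3 clusters was 0.601. Only seed 8, which gave 4 clusters, was below 0.49, at 0.415. Leaving these genes out thus changed the clusters more than any seed that gave 3 clusters.

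Mrc1 was at a CPM of 10 or more in 77 cells. If these were border-associated macrophages inside the gate, most of them would be expected to carry further markers of that type, but 1 of the 77 (1.30%, 0.033 to 7.02) had 3 or more of 8 specific markers and 43 had none. Mrc1 was among the leading genes of cluster 2, at 292 pooled CPM against 97.8 in cluster 3; Stab1, which the phagocytic list also holds, was at 469 and 231.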
